A study of Mus musculus with 4 samples.

How the data were processed

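CUT&RUN was performed on GC B cells sorted from lymph nodes of wild-type mice. Per the labels' protocols, the cells of each mouse were split between a rabbit monoclonal antibody to SNF2H (the SMARCA5 protein) and a rabbit isotype antibody, cut with protein A/G-MNase, and the released fragments were sequenced as paired ends. The 4 libraries formed 2 groups of 2, SMARCA5 antibody and isotype, taken from the sample titles. The labels do not state that libraries 1 and 2 come from different mice, so agreement between lists measures the spread between these samples, which may be technical in part.

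Reads were aligned with Bowtie2 to mm10 and peaks were called with MACS2, per the submitters' processing notes, which give no versions. Options, duplicate handling and treatment of reads that align to several places are not given in the sources used here. Per the labels, each peak list compares 1 SMARCA5 library with the isotype library of the same number, so replicates were not pooled. The deposited lists give for each peak a fold enrichment, which is a ratio of SMARCA5 signal over background at the summit, a −log10 p and a −log10 q. They also hold a deposited score, which equalled the whole part of 10 times −log10 q in all 13213 and 9328 peaks, and the position of the summit. The least −log10 q was 1.30 in list 1 and 1.31 in list 2, which corresponds to a q threshold of 0.05. The peak lists hold no read totals, so depth is unknown, and confidence intervals on shares of peaks or genes cover counting error only. Unused columns of per-sample values numbered 0.

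Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 represents, with 49980 genes on named chromosomes, of which 21887 were protein-coding nuclear genes. The table gives the start and end of each gene but no strand, so the planned window around transcription start sites was replaced by 1 kb around either gene end. No genome sequence was used, so the planned test of 20 sequence motifs and the matching of gene lists on CpG content were not run. Exons, introns and UTRs were not told apart, because the table gives no transcript models. Of the fixed gene symbols, 1 (Ighd) did not match a protein-coding gene and was left out.

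A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Overlapping peaks were merged into shared regions, with the highest fold enrichment of each list. The number of shared peaks and the share at gene ends were compared with 1000 random placements (100 for an overlap of 50% of the shorter peak, 200 for classes of location) that kept each peak's chromosome and width within the range spanned by genes and peaks. Assembly gaps were not excluded, which lets some placements fall where no peak can. These tests were 1-sided permutation tests. Gene lists were compared with all other protein-coding genes by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 20 lists at a threshold of 0.05. Genes are not independent replicates, so these p-values say only whether a list stands apart within these peak lists. Medians of fold enrichment were compared by 2-sided permutation of class labels (100000), and rank correlation by 10000 permutations. Regions over 10 kb from a protein-coding gene end were counted within 50 kb of listed genes and compared with 10000 random lists of genes matched on decile of gene length, by a 2-sided permutation test. Shares have exact Clopper-Pearson 95% intervals.

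The 20 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named 12 genes in every case, of which 1 is not reported here (the others are Smarca5, Bcl6, Prdm1, Irf4, Xbp1, Pax5, Bach2, Myc, S1pr2, Ctcf and Rad21). It added up to 3 genes per list with the highest mean percentile of fold enrichment at a shared gene-end peak, the 10 highest shared regions at gene ends and the 5 highest over 10 kb from any gene end. Other members of lists with up to 9 hits, and the genes named for regions away from gene ends, were named after their values were seen. Alternatives covered the overlap that counts as shared, the window, the −log10 q threshold, the replicates and the random placements. The list comparison away from gene ends, tRNA genes, local placements, lists matched on gene density, a summit of both lists at the gene end, distal regions counted once per list, and removal of mitochondrial and Y peaks were added after the data were seen.

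The functions were tested on simulated lists 1 and 2 in which 3000 peaks were placed in both: all 3000 were recovered with 38 chance overlaps, and all 200 genes given a shared peak at an end were found among 21887, with 115 others by chance. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.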

Results

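SMARCA5 (also called SNF2H) is an ATPase of the ISWI family of chromatin remodellers, which slide nucleosomes along DNA. Its binding was profiled by CUT&RUN, in which an antibody directs a nuclease to cut and release the DNA around a bound protein. The cells were wild-type germinal centre (GC) B cells, the proliferating B cells of an immune response, from inguinal lymph nodes of mice 7 days after immunization with the antigen KLH in an adjuvant. The data comprised 4 libraries, 2 made with the antibody to SMARCA5 and 2 with a rabbit isotype antibody that measures background. The files used were 2 peak lists, each giving the regions where SMARCA5 library 1 or 2 exceeded the isotype library of the same number. List 1 held 13213 peaks covering 5.84 Mb and list 2 held 9328 peaks covering 3.97 Mb, with a median peak width of 347 bp in both. Sequencing depth is unknown, because peak lists carry no read totals, so the 1.42-fold difference in peak number cannot be set against it. Fold enrichment over isotype is the authors' own value for each peak and is used here only within a list. Its median was 5.26 in list 1 (interquartile range 4.37 to 6.76) and 4.91 in list 2 (4.19 to 5.88). Single values carry no replicate error, and the spread between lists is given by printing both. All coordinates are those of the mouse build mm10.

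The first comparison asked whether the 2 peak lists mark the same places. They shared peaks at the ends of B cell genes, among them Bcl6, the master regulator of the GC program, Ezh2, a histone methyltransferase GC B cells depend on, and Pax5, which maintains B cell identity. Of the 13213 peaks of list 1, 4831 (36.6%, exact 95% confidence interval 35.7 to 37.4) overlapped a list 2 peak by at least 1 bp. Random placement of list 2 on its chromosomes gave a mean of 46.9 and at most 70, so the observed number was 103 times higher (1-sided permutation p = 0.001, the smallest that 1000 placements can give). Placing each peak within 20 to 100 kb of its own position, an alternative added after the data were seen, gave a mean of 168, and the observed number was 28.8 times higher. Neither kind of placement kept peaks at gene ends, where 40.6% of list 1 and 37.6% of list 2 summits lay. Both ratios therefore mix agreement at single sites with a preference for gene ends common to the lists. Counted from list 2, 51.7% of its peaks were shared. The overlaps merged into 4717 shared regions, whose summits in the lists lay a median of 94 bp apart, and 52.5% lay within 100 bp.

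Sharing differed with peak strength. In list 1, 13.7% of the lowest decile of peaks by fold enrichment were found in list 2 (95% interval 11.9 to 15.7) against 79.7% of the highest decile (77.4 to 81.9). In list 2 the corresponding shares were 15.01% and 89.9%. Among list 2 deciles the share did not climb steadily, since the third decile (17.8%) lay below the second decile (45.6%). Across the 4717 shared regions, fold enrichment in the lists was correlated with Spearman's rho 0.31 and Pearson's r 0.36 (permutation p = 1e-04 for rho, the smallest that 10000 permutations can give). This correlation is across regions, which are not independent replicates. Among regions with −log10 q of at least 5 in both lists, rho was 0.16.

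**Figure D1:**
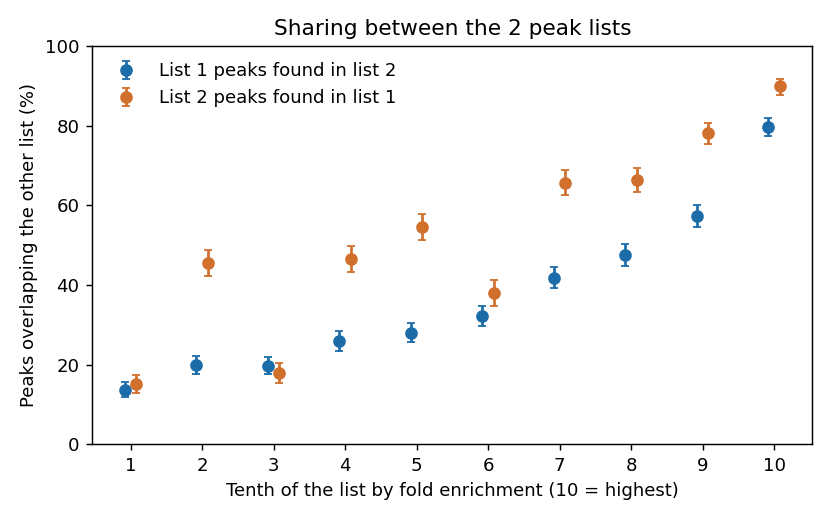
Share of peaks (%) that overlap a peak of the other list, for each decile of list 1 (blue) and list 2 (orange) ordered by fold enrichment; bars are exact 95% confidence intervals. The lowest and highest deciles are 13.7% and 79.7% in list 1 and 15.01% and 89.9% in list 2.

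The next comparison asked where the SMARCA5 signal lies. It was concentrated at the ends of protein-coding genes: 2458 of the 4831 shared list 1 peaks (50.9%, 95% interval 49.5 to 52.3) had their summit within 1 kb of a gene end. Random placement put 3.22% there (at most 3.95%), a 15.8-fold difference (1-sided permutation p = 0.001, the smallest possible). Against placements near each peak's own position, which put 7.44% there, the difference was 6.84-fold. Peaks of list 1 and list 2 taken alone had 40.6% and 37.6% of summits at gene ends, and peaks that were not shared had 34.8% in list 1 and 23.5% in list 2. A gene end here is either boundary of the gene model, because the annotation used carried no strand, so transcription start and termination sites were not told apart.

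Summits sat close to the boundary. Among those within 1 kb, the median distance was 186 bp in list 1 and 206 bp in list 2, and 65.0% and 59.7% lay within 250 bp, where an even spread would put 25.04%. In the lists 59.3% and 59.1% of them lay inside a gene. Random placement of list 1 also put more summits inside, with 0.19% in the 100 bp just inside and 0.15% in the 100 bp just outside. The shares inside a gene were not tested against placement. Summits formed a maximum on either side of the boundary, with a dip only just outside it. Of all list 1 peaks, 7.37% lay 100 to 200 bp inside and 4.96% 100 to 200 bp outside. The 100 bp just outside held 3.43% and the 100 bp just inside 6.09%. In list 2 the corresponding shares were 6.44%, 3.86%, 3.09% and 4.76%. Of 21887 protein-coding genes, 2881 (13.2%) had a shared peak at an end. Of the 2796 such genes long enough for the windows not to overlap, 39 (1.39%) had one at both ends. Shared peaks inside gene bodies over 1 kb from an end made up 26.3% against 38.9% by placement. Those outside protein-coding gene ends, gene bodies and other annotated genes made up 14.9% against 48.5%.

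**Figure D2:**
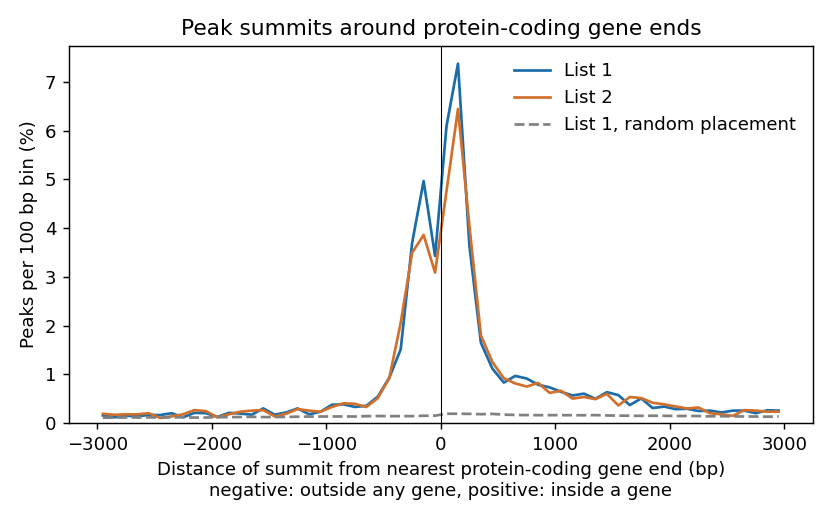
Share of peaks (%) per 100 bp bin by the distance (bp) of the summit from the nearest protein-coding gene end, for list 1 (blue), list 2 (orange) and random placements of list 1 (dashed grey); negative distances lie outside genes. Both lists peak within 250 bp of the end, where 65.0% and 59.7% of the summits within 1 kb fall.

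Shared regions were ranked by fold enrichment in both lists. The highest at a gene end was on chromosome 6 from 85450963 to 85452398, at Cct7, a subunit of the CCT chaperonin, and at Pradc1, with fold enrichment 19.1 in list 1 and 17.2 in list 2. It was followed by regions at Smim7 and Tmem38a (16.5 and 15.9), Carm1, an arginine methyltransferase acting on histones (15.99 and 15.4), and Cep97, a centrosomal protein (16.7 and 14.1). Regions at Tpmt and the histone demethylase gene Kdm1b (15.5 and 14.3), at Cblb, a ubiquitin ligase of lymphocyte signalling (15.9 and 13.6), and at Aldh16a1 (17.3 and 13.04) came next. The remaining ones lay at Znfx1 and the noncoding RNA gene Zfas1 (14.1 and 17.8), at the remodeller gene Chd1l with Fmo5 (18.4 and 11.3), and at Rex1bd (26.9 and 10.9). Among 772 shared regions over 10 kb from any gene end, one of the 5 strongest lay 15919 bp from Cxcr4, the chemokine receptor that places GC B cells in the dark zone (chromosome 1, 128607825 to 128608528, 13.1 and 11.7). The others were 11010 bp from Rpap3 (13.5 and 13.6), inside Prkce on chromosome 17 from 86336635 to 86337702 (13.1 and 13.4), inside Heg1 (15.7 and 10.5), and inside Pakap on chromosome 4 (16.4 and 10.1).

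Genes of the GC program and of B cell identity had shared peaks at their ends more often than other genes. Of 20 GC B cell genes, 7 did (35.0%, against 13.1% of other genes): Bcl6, Ezh2, Cxcr4, Mybl1, Foxo1, Eaf2 and Hhex. Of 20 B-lineage transcription factors, 7 did as well (35.0%): Pax5, Ebf1, Tcf3, Pou2f2, Pou2af1, Elf1 and Foxo1, which belongs to both lists. The peak at Eaf2 had fold enrichment 10.0 and 8.42, that at Ezh2 9.65 and 6.89, and that at Mybl1 7.36 and 7.04. The peaks at Pou2af1, a B cell coactivator of octamer factors, had 8.68 and 7.61, and those at Elf1 7.88 and 6.84. Both lists passed the 2-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 20 gene lists (adjusted p = 0.0315 each). Neither passed among peaks with −log10 q of at least 5 (4 of 20 genes, adjusted p = 0.0821, and 2 of 20, adjusted p = 0.489, exact tests), and the transcription factors did not with a 250 bp window (4 of 20, adjusted p = 0.252, exact test). The other genes include 1110 olfactory receptor genes, none with a shared peak. Shares were 47.4% for chromatin remodellers, 35.5% for ribosomal protein, 33.3% for oxidative phosphorylation and 21.9% for cell cycle genes. The comparison was not matched on expression or accessibility. It therefore cannot separate a preference for GC or B cell genes from signal at active genes in general.

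Chromatin remodellers had shared peaks at 9 of 19 genes (47.4%, 95% interval 24.4 to 71.1, Fisher's exact test, adjusted p = 0.0021). They included Smarca5 itself and genes whose products pair with it in ISWI complexes: Baz1b (10.9 and 11.97), Baz2a (11.9 and 8.45) and Rsf1 (8.75 and 7.97). Ino80, Rbbp4, Hdac1, Arid1a and Smarcb1 were the other members with one. Baz1a, Baz2b, Bptf, Cecr2, Chrac1, Pole3, Rbbp7 and Smarca1, also genes of ISWI complexes, had no shared peak at an end. The Baz2a peak is the same region as that of the ATP synthase gene Atp5b, on chromosome 10 from 128090495 to 128091425. Ribosomal protein genes had shared peaks at 11 of 31 (35.5%, adjusted p = 0.0068, exact test), with Rps14 (15.8 and 8.69), Rps23 (11.8 and 7.61) and Rps25 (10.4 and 7.97) the strongest. Replication-dependent histone genes had them at 20 of 64 (31.3%, adjusted p = 0.0014, exact test). Because histone genes are clustered, these rested on 16 distinct regions, among them those at H2ac18 (10.0 and 11.7), H4c8 (9.98 and 7.76) and H4c3 (9.21 and 8.27). Oxidative phosphorylation genes had them at 8 of 24 (33.3%, adjusted p = 0.0315, exact test), with Cox4i1 at 8.96 and 5.88 and Ndufs1 at 4.64 and 9.45. Among peaks with −log10 q of at least 5 only ribosomal protein genes were still higher (19.4%, adjusted p = 0.0296, exact test). The share of oxidative phosphorylation genes there lay below that of other genes (1 of 24, 4.17%, adjusted p = 1, exact test), and the list was also not called against lists matched on gene density (adjusted p = 0.0846, permutation) or in list 2 alone (adjusted p = 0.0534, exact test).

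Genes of antibody secretion and B cell signalling had shared peaks at shares between 22.7% and 33.3% that did not pass the exact test after adjustment. Of 22 antibody-secreting cell genes, 6 had one (27.3%, adjusted p = 0.119, exact test), the strongest at Sec11c, a subunit of the signal peptidase (11.2 and 12.2), Ell2, an elongation factor (10.0 and 7.58), and Herpud1, of endoplasmic reticulum protein quality control (9.48 and 5.98). CD40 and NF-kB signalling had 6 of 18 (33.3%, adjusted p = 0.0587, exact test), with Map3k14, the NF-kB inducing kinase (12.9 and 8.09), Birc3 (12.6 and 7.08) and Tnfaip3 (7.16 and 5.19). Antigen presentation had 5 of 16 (31.3%, adjusted p = 0.109, exact test), with Tap1 (12.6 and 8.51), Cd86 (9.59 and 6.89) and H2-Ob (12.5 and 5.52). B cell receptor signalling had 5 of 22 (22.7%, adjusted p = 0.265, exact test), with Malt1 (14.6 and 8.42), Lyn (8.999 and 9.23) and Syk (9.31 and 4.47). Naive and memory B cell genes had 4 of 14 (28.6%, adjusted p = 0.169, exact test), with the integrin gene Itga4 (11.2 and 11.7), Btla (4.997 and 6.34) and Cd72 (13.6 and 3.80). In list 1 alone each of these 5 lists was higher than other genes, and in list 2 alone antibody-secreting cell genes (adjusted p = 0.0267) and CD40 and NF-kB signalling (adjusted p = 0.0264) were, by the same exact test. With a 5 kb window B cell receptor signalling (12 of 22, 54.5%, adjusted p = 0.00059) and antigen presentation (8 of 16, adjusted p = 0.0082) were higher, and with a 250 bp window CD40 and NF-kB signalling was (6 of 18, adjusted p = 0.0222), by the same exact test.

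Cell cycle genes had shared peaks at 7 of 32 (21.9%, adjusted p = 0.261, exact test), among them the mitotic kinase genes Aurka (9.08 and 8.66) and Aurkb (10.3 and 7.04) and the cyclin gene Ccna2 (9.17 and 6.48). DNA repair and class switching genes had them at 6 of 23 (26.1%, adjusted p = 0.171, exact test), including Ung, a uracil glycosylase of base excision repair (15.6 and 5.75), Brca1 (8.63 and 6.19) and the mismatch repair gene Msh6 (7.16 and 5.52). CTCF, cohesin and architecture genes had them at 4 of 14 (28.6%, adjusted p = 0.169, exact test): Ctcf, Pds5a (6.57 and 10.7), Zfp143 (7.31 and 4.87) and Maz (7.38 and 4.85). In list 1 alone these 3 lists too were higher than other genes.

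Genes of other cell types rarely had a shared peak. Olfactory receptor genes had none at 1110 genes, lower than the 13.9% of other genes (95% upper bound 0.332%, Fisher's exact test, adjusted p = 4.6e-69). These genes lie in clusters, so the exact p and the bound treat linked genes as independent. Against random lists matched on gene density the adjusted permutation p was 0.004. Markers of T cells had 1 of 20, at Cd2 (5.29 and 5.69), and markers of myeloid and dendritic cells had 1 of 18, at the chemokine receptor gene Xcr1 (7.81 and 9.23). Stromal and endothelial markers (15 genes), neuronal genes (16) and liver genes (16) had none. With lists this short, the exact upper bounds are 21.8%, 20.6% and 20.6%, so a lower share than in other genes was not detectable (adjusted p = 0.282 each, exact test; 0.504 for T cell and for myeloid markers). In list 1 alone, stromal and endothelial markers (adjusted p = 0.0191, exact test) and neuronal genes (adjusted p = 0.0132, exact test) were lower. Myeloid markers (4 of 18, 22.2%, adjusted p = 0.795), T cell markers (3 of 20, adjusted p = 0.333) and liver genes (1 of 16, adjusted p = 0.0965) were not called there by the same exact test, where 26.5% of all genes had a peak. With a 5 kb window myeloid markers also had 4 of 18 (adjusted p = 0.558, exact test).

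**Figure D3:**
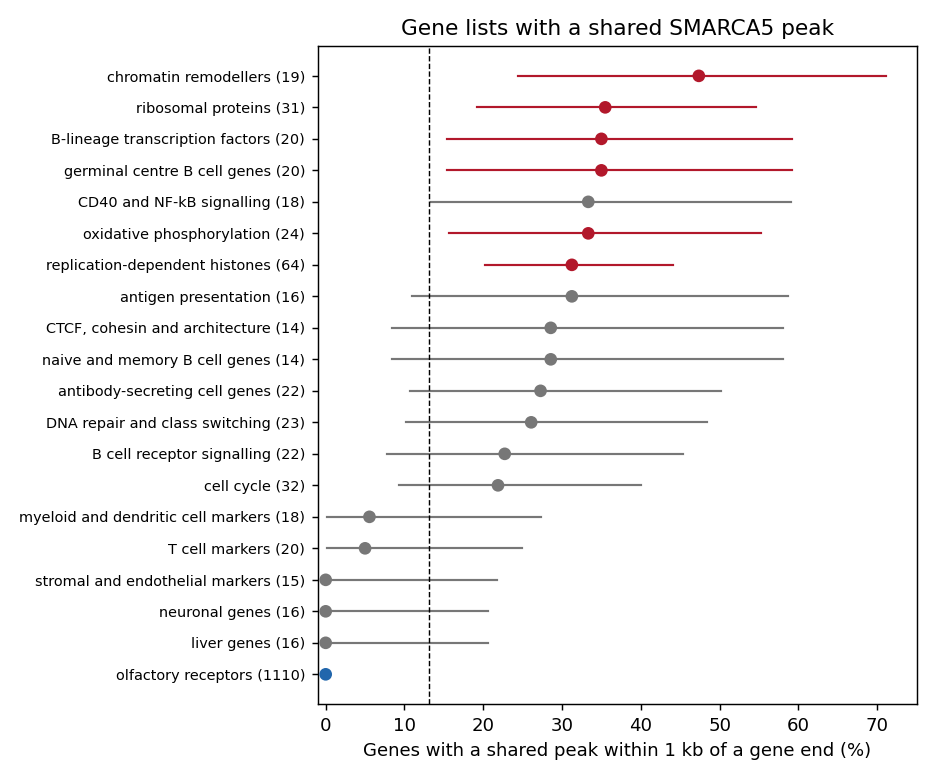
Share of genes (%) with a shared peak within 1 kb of a gene end for each of the 20 gene lists (number of genes in parentheses); lines are exact 95% confidence intervals and the dashed line is the share among all 21887 protein-coding genes, 13.2%. Red lists were higher and blue lower than other genes after adjustment; grey lists were not called, and chromatin remodellers lie at 47.4%.

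Genes central to the GC and plasma cell decision differed in where peaks lay. Smarca5 had a shared peak at its end on chromosome 8 from 80739046 to 80739849 (4.73 and 8.39). Bcl6 had one at its end on chromosome 16 from 23988419 to 23989378 (8.63 and 4.84) and a further pair inside the gene (6.75 and 5.18, and 7.58 and 6.13). Pax5 had one at its end (chromosome 4, 44710785 to 44711294, 5.19 and 7.04) and 3 inside the gene at least 37823 bp from an end, and Ctcf had one at its end on chromosome 8 from 105635926 to 105636840 (10.96 and 3.69). Irf4, a transcription factor of both GC entry and plasma cell differentiation, had an end peak in each list, but none was shared. A shared region lay inside the gene (7.25 and 6.30). Myc, Xbp1 and Bach2 had an end peak in list 1 only. Shared regions lay 2015 bp from Myc (5.15 and 4.92) and 8261 and 34965 bp from Xbp1 (5.17 and 3.68, and 5.01 and 4.83). Bach2, a repressor of plasma cell differentiation, also had 4 shared regions within 50 kb, including one inside the gene 1153 bp from its end. Prdm1, which encodes Blimp-1, the driver of plasma cell differentiation, had no end peak in either list and no shared region within 50 kb, and the same held for the cohesin gene Rad21. S1pr2, which confines GC B cells to the follicle, had no end peak and a shared region 13151 bp away (10.6 and 5.75). That region was not among those over 10 kb from a protein-coding gene end, so the end of another gene lay nearer to it. Regions were matched to the genes of this paragraph by position only.

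Peaks at gene ends had higher fold enrichment than peaks elsewhere in list 1, with medians of 5.73 and 5.01, a difference of 0.72. In list 2 the medians were 5.15 and 4.72, a difference of 0.42. Both had a 2-sided permutation p of 1e-05, the smallest that 100000 permutations can give. Among shared peaks only, the difference was 0.56 in list 1 (permutation p = 1e-05) and was not called in list 2 (0.01, permutation p = 0.196), nor in list 2 among peaks with −log10 q of at least 5 (0.04, permutation p = 0.0929).

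The X chromosome carried fewer peaks per Mb than any autosome. In list 1 it had 1.23 peaks per Mb against 5.32 over the autosomes, whose lowest was 3.78 (chromosome 14) and highest 9.40 (chromosome 11), a ratio of 0.231. In list 2 it had 0.785 against 3.76, a ratio of 0.209. Per 100 protein-coding genes, X had 21.7 peaks in list 1 against an autosomal range of 46.4 to 74.5, and 13.9 in list 2 against 30.5 to 55.5. The ratio among shared peaks was 0.138. X was set against the range over the autosomes without a test. Sex and copy number of X were not taken into account, so fewer copies were not told apart from less binding.

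Away from gene ends, shared regions gathered around genes of several of the B cell lists, a comparison added after the data were seen. The random lists here were matched on gene length but not on gene density, which limits where regions over 10 kb from gene ends can lie. Nor were they matched on expression or accessibility. Within 50 kb of 20 B-lineage transcription factor genes lay 30 of the 1249 shared regions over 10 kb from a protein-coding gene end, 9.79 times the mean of random lists matched on gene length, and 13 of the 20 genes had at least 1. Ets1 had 5, Foxp1 and Mef2c had 4 each, and Ikzf1, which encodes Ikaros, had 3, the strongest on chromosome 11 from 11788046 to 11789028 (9.67 and 18.3). Naive and memory B cell genes had 12 regions (11.4-fold), including 3 near S1pr1 and 2 near Cd38. Antigen presentation genes had 11 (9.63-fold), but these were 6 distinct regions counted for several clustered genes, and with each region counted once per list the excess was not called (5.13-fold, adjusted permutation p = 0.0571). B cell receptor signalling genes had 22 (7.84-fold), including 4 around Pik3ap1, 3 near Malt1 and 2 near Blnk, the strongest of the last at 20.7 and 9.30. GC B cell genes had 14 (7.43-fold), including 4 near Cd83, 3 near Cxcr4 and the 4 of Mef2c, which belongs to both this list and the transcription factors, so these regions count in both. Adjusted permutation p-values over 20 lists were 0.0008 for these lists, except antigen presentation with 0.0013. CD40 and NF-kB signalling genes had 2 (1.24-fold, adjusted permutation p = 1) and DNA repair and class switching genes 4 (1.52-fold, adjusted permutation p = 0.915).

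Ribosomal protein and oxidative phosphorylation genes, called at gene ends, were not called here, although the difference between the results was not tested. Ribosomal protein genes had 2 such regions (1.24-fold, adjusted permutation p = 1) and oxidative phosphorylation genes 1 (0.71-fold, adjusted permutation p = 1). Chromatin remodellers had 10 (4.03-fold, adjusted permutation p = 0.0166), of which 5 lay near Bptf, a subunit of the NURF complex. Antibody-secreting cell genes had 7 (3.64-fold, adjusted permutation p = 0.0911), including 2 near Tnfrsf13b. CTCF, cohesin and architecture genes had 4 (2.20-fold, adjusted permutation p = 0.618) and cell cycle genes 3 (1.32-fold, adjusted permutation p = 1). T cell markers had 2 and myeloid markers 1, while stromal, neuronal and liver genes had none. Histone genes were called (11.4-fold, adjusted permutation p = 0.0008), but their 18 regions were 3 distinct ones counted for several clustered genes, and counted once they were not called (1.96-fold, adjusted permutation p = 0.804). One of the 3, on chromosome 13 from 23516772 to 23520047, also had 5 tRNA genes inside it or within 1 kb. Olfactory receptor genes were lower (0.52-fold, adjusted permutation p = 0.034), which was lost with a 20 kb flank (adjusted permutation p = 0.076) and among peaks with −log10 q of at least 5 (adjusted permutation p = 0.228). Under the stricter threshold chromatin remodellers (adjusted permutation p = 0.181) and naive and memory B cell genes (adjusted permutation p = 0.0707) were also no longer called, and chromatin remodellers were not with a 20 kb flank (adjusted permutation p = 0.0623) or in list 1 alone (adjusted permutation p = 0.081) either.

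Transfer RNA genes, transcribed by RNA polymerase III, stood out among gene classes in a comparison added after the data were seen. Of 408 nuclear tRNA genes, 150 (36.8%, exact 95% interval 32.1 to 41.6) had a shared peak within them or within 1 kb, against 0.41% by random placement (at most 2.94%, 1-sided permutation p = 0.001, the smallest possible). These genes shared 97 distinct regions. With a 250 bp window the number was 78 (19.1%), and with −log10 q of at least 5 it was 105 (25.7%). Peaks there had a median fold enrichment of 7.74 against 5.24 elsewhere in list 1 and 6.58 against 4.90 in list 2 (permutation p = 1e-04 each, the smallest possible), were wider (median 743 against 345 bp in list 1) and were shared more often (69.9% against 36.2% in list 1, 91.8% against 51.2% in list 2). The strongest regions were on chromosome 2 from 57181562 to 57183049 (21.5 and 13.4, 2 tRNA genes), on chromosome 13 from 23516772 to 23520047 (21.8 and 11.05, 5 tRNA genes, next to histone genes) and on chromosome 13 from 21199806 to 21200935 (19.6 and 11.1). Occupancy varied by chromosome: 34 of 52 tRNA genes on chromosome 11 and 33 of 105 on chromosome 13 had a shared peak, but 2 of 53 on chromosome 6 and 1 of 17 on X.

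Other short RNA gene classes had lower shares. Among snRNA genes 26 of 1004 (2.59%) had a shared peak, among miRNA genes 26 of 1228 (2.12%), among snoRNA genes 16 of 1340 (1.19%), each above placement (0.39%, 0.38% and 0.41%, 1-sided permutation p = 0.001 each), and among rRNA genes 0 of 63 (95% upper bound 5.69%). None of 394 variable gene segments of antigen receptor loci had one (95% upper bound 0.932%), where placement gave 0.38%, so a deficit was not detectable. Over 5 kb from protein-coding gene ends, miRNA genes (6 of 809, 0.74%, permutation p = 0.0959) and snoRNA genes (1 of 1064, 0.094%, permutation p = 0.986) did not pass the test against placement, while snRNA genes did (13 of 851, 1.53%, permutation p = 0.001).

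**Figure D4:**
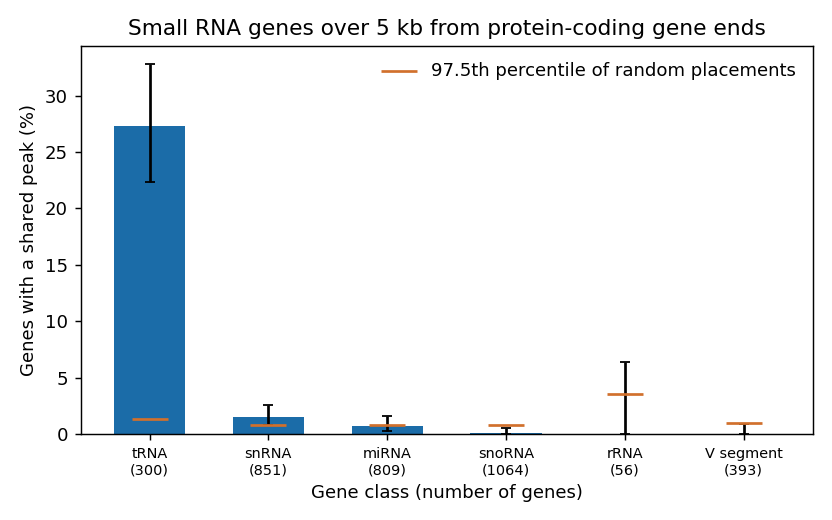
Share of genes (%) with a shared peak inside them or within 1 kb, for short RNA gene classes and variable gene segments over 5 kb from protein-coding gene ends (number of genes in parentheses); bars are shares, black lines exact 95% confidence intervals and orange marks the upper limit of the central 95% of random placements. The tRNA bar stands at 27.3% and its placement mark at 1.33%.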

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

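The mitochondrial test here was chosen only after the result was seen. The mitochondrial genome, which the comparisons above do not address, carried 4 broad peaks over isotype. List 1 had one from 43 to 6577 with fold enrichment 3.68 and one from 10859 to 16224 with 4.76, and list 2 had one from 99 to 6534 with 3.18 and one from 10889 to 16185 with 3.25. They ranked 11 and 3 in list 1 and 7 and 4 in list 2 by −log10 q, but 12367 and 8491, and 9311 and 9304, by fold enrichment.

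In both lists the mitochondrial peaks stopped around a stretch of 4281 bp in list 1 and 4354 bp in list 2 that holds COX2, ATP8, ATP6, COX3, ND3 and ND4L. The edges of the stretch differed by at most 43 bp between the lists. On chromosome 1 from 24612404 to 24614651, the pseudogenes Gm10925 and Gm10222 have the lengths of ATP6 and ND4L (681 and 297 bp) and span 2248 bp, where those genes span 2247 bp. A candidate explanation is that reads of this stretch align equally well to a nuclear copy and were lost there, but it stays open. The matching pseudogenes cover the part from ATP6 to ND4L and nothing bears on COX2 and ATP8, sequences were not compared, and list 1 had 1 peak within the nuclear copy and list 2 had 0. Why mitochondrial signal exceeded isotype stays open, and no biological explanation was tested.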

How the results depend on the processing

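The comparisons of distal regions, tRNA genes, local placements and density-matched lists were chosen only after the results were seen. No paired analysis was possible because each peak list already contrasts a SMARCA5 library with the isotype library of the same number, and no test between libraries could be made. CpG-matched gene lists and all 5 alternatives of the motif test were not run, since no genome sequence was used. The share of shared peaks (29.1 to 51.7%) and the share at gene ends (34.3 to 65.0%) stayed above placement under every alternative run. With −log10 q of at least 5, the number of shared peaks was 1441, because fewer peaks entered. The number of gene lists higher than other genes was then 1, and oxidative phosphorylation lost its call and turned below other genes at 4.17%, 1 of 24 genes (adjusted p = 1, exact test); fewer peaks entered there too. Without replicate 1 or 2, between 7 and 14 lists were higher and between 1 and 3 lower, the upper values resting on list 1 alone. Of 140 results for single lists, 117 stayed as in the main setting, most of them for lists not called there. A call was gained in 15 and lost in 7, besides oxidative phosphorylation with −log10 q of at least 5. The gene-end difference of list 2 was 0.01458 among shared peaks and 0.04403 with −log10 q of at least 5, neither called; the cause was not tested. The X to autosome ratio was 0.164 in list 1 and 0.135 in list 2 with −log10 q of at least 5, and 0.138 for shared peaks in either list; the cause was not tested. Distal regions gave 0 lower lists with a 20 kb flank and 0 with −log10 q of at least 5, against 1. With each region counted once, 5 lists were higher. In all, 92 of 100 single results for distal regions stayed as in the main setting, most of them for lists not called there, and 8 lost a call. Depth is unknown, so it limits every statement about a missing peak.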

Other observations

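The comparison of paired gene ends and the account of Y peaks were chosen only after the results were seen, and so was the choice of tRNA genes as a pattern. Technical explanations for the peaks at tRNA genes were weighed. Nearby protein-coding gene ends do not account for all of them, since among 300 tRNA genes over 5 kb from any such end 82 (27.3%) had a shared peak, where the central 95% of placements reached at most 1.33%. That share was below the 36.8% of all 408 tRNA genes, so a part played by such ends stays open. Reads shared between gene copies were tested on other multicopy classes: of 907 snRNA and rRNA genes over 5 kb from such ends 13 (1.43%, interval 0.77 to 2.44) had one, below the interval of tRNA genes (22.4 to 32.8), although the snRNA genes among them (1.53%) also exceeded placement (0.39%). How alike the copies are within each class was not measured, and signal that follows open chromatin in general stays open, as no accessibility data were analysed. No biological explanation was tested, so binding of SMARCA5 at active tRNA genes may be put forward only as a hypothesis.

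Most list 1 peaks were not found in list 2. If these were weak peaks near the calling threshold, the top decile by fold enrichment should be over 80% shared and the lowest under 30%, as set before the shares were seen. The values were 79.7% (95% interval 77.4 to 81.9) and 13.7%, so the interval spans the bound and the test leaves the explanation open, while the difference between the deciles goes its way. The calling threshold was set on q, which can rank peaks otherwise than fold enrichment, as it did for the mitochondrial peaks. A decile of fold enrichment is therefore only an indirect measure of nearness to the threshold. A difference in depth between libraries could act the same way and cannot be told apart from it, because depth is unknown.

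Shared peaks with ends of 2 or more protein-coding genes within 1 kb had a median fold enrichment of 7.00 against 6.69 for those with 1 in list 1 (permutation p = 0.0609) and 5.75 against 5.52 in list 2 (permutation p = 0.0246). On chromosome Y, list 1 had 6 peaks and list 2 had 5, all between 90740348 and 90809110, and 4 in each list were shared.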
